A study of Mus musculus with 27 samples.

How the data were processed

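Mouse ES cells of the CJ7 line were grown with LIF and serum, per the labels' protocols. For the small RNA samples the labels describe gel selection of RNA of 18 to 40 nt, a SOLiD small RNA library kit and sequencing on a SOLiD instrument. The submitters' processing notes name cutadapt, Bowtie and the genome build mm9. Their versions and settings, and the handling of reads that match several places, are not given in the sources used here. The data analysed were 4 microRNA tables, 1 per genotype. Each deposited table gives, per the file headers, the count of reads per mature microRNA locus and the same value as reads-per-million (RPM), for miRBase release 20. Coordinates were read as mm9, the build that the submitters' processing notes name. Dividing the deposited counts by the RPM values gave the denominators the authors used: 246316316 for wild-type, 267248746 for Eed-/-, 243895676 for Ezh2-/- and 62259756 for Jarid2-/-. MicroRNA counts were 9.66%, 15.8%, 13.2% and 13.6% of them.

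Columns were assigned to genotypes by their names. Those of Ezh2-/- and Eed-/- name the gene, and that of Jarid2-/- carries the older gene name Jumonji. The wild-type assignment is the least direct, because that column names the parental CJ7 line and no mutant gene. The labels list 2 small RNA samples for wild-type, Eed-/- and Ezh2-/-, and no source says whether a column pools both or holds 1. All columns were assigned. The chromatin, messenger RNA and remaining small RNA measurements were not analysed here.

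The 2035 loci carry 1900 mature names, and 77 names have more than 1 locus. Of 187 values of such names with at least 100 counts, 174 were within 5% of each other across loci, which counting at each locus and an even split between loci would both give. Loci of microRNAs with several copies or same-numbered relatives, called multi-copy here, were left out in 1 alternative. The gene table used here is for GRCm38, and 49 of 1693 loci matched by name fell inside its hairpins, so all coordinates are those of the deposited tables and no annotation of exons or introns was used.

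CPM was the deposited count in counts-per-million of the column's microRNA counts. Log2 ratios used CPM plus a pseudocount of 1 CPM, which understates the differences of low loci. A locus was tested for size when 1 of the 2 columns had at least 10 counts and called when the ratio was at least 2-fold. Folds without pseudocount came with exact conditional binomial 95% intervals and shares with Clopper-Pearson intervals. A count of 0 was set at a floor of 3 counts per column where a bound was needed. The planned tests across libraries (the quasi-likelihood test of edgeR with DESeq2 as the alternative, and gene set tests) were replaced by the plan's fallback for 1 value per genotype, ratios with no test. For each microRNA group the median log2 ratio was set against 10000 random lists (1000 in alternatives) of the same size matched on mean expression in 10 bins, and its percentile describes these columns only.

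The comparisons, the alternatives, the groups and the rule for named microRNAs were fixed before the data were examined. The 13 groups were the Gtl2-Rian-Mirg cluster, the miR-290, miR-302 and miR-17 family clusters, the let-7 family, Hox cluster microRNAs, neural, muscle and mesenchymal, epithelial and endodermal, and blood cell microRNAs, other imprinted microRNAs, the Sfmbt2 intronic cluster, and the miR-29 and miR-34 families. The named microRNAs were the 10 highest and 10 lowest ratios per mutant against wild-type among loci with at least 50 counts in 1 of the 2 columns, the 5 highest and lowest between mutants, and the 4 most abundant members of each group (10 for the Gtl2-Rian-Mirg cluster). The division of the Gtl2-Rian-Mirg locus into 3 parts, the comparison of 5p and 3p arms and the scan of genomic clusters (at least 4 hairpins with gaps up to 10 kb) were added after the values were seen.

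The alternatives fixed in advance were TMM factors from edgeR 4.0.16, median-ratio size factors from DESeq2 1.42.0, scaling on loci outside the Gtl2-Rian-Mirg and miR-290 clusters, a filter of 1 or 100 counts, a pseudocount of 0.1 or 10, arms and copies summed per hairpin, multi-copy loci left out, cluster membership by position, and shares without the miR-290 cluster in the denominator. Scaling by the RPM denominators, 1 value per mature name and thinning to the Jarid2-/- total were added after the data were seen. Overlaps between mutants were set against independent lists and against 100 simulated unchanged libraries per genotype drawn from the wild-type profile and compared with the deposited wild-type counts.

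The procedure was tested on simulated counts for the 2035 loci in each contrast with wild-type, with 50 loci at each of 4 sizes. At log2 changes of -3, 1.5 and 3, 100% of loci were called. At -1.5, 92% were called for Eed-/-, 92% for Ezh2-/- and 94% for Jarid2-/-, and 0% of the 809, 780 and 752 tested unchanged loci were called. The changed loci were drawn from those with at least 100 wild-type counts, leaving out the most abundant. Simulated counts carried counting error only, and the known shift in totals was subtracted before calling. These rates therefore do not cover changed loci with fewer counts or variation between libraries. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.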

Results

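The series compared mouse embryonic stem (ES) cells of the CJ7 line in 4 genotypes: wild-type, Eed-/-, Ezh2-/- and Jarid2-/-. Eed and Ezh2 are core subunits of the Polycomb complex PRC2, a histone methyltransferase of silent chromatin, and Jarid2 is a cofactor that helps bring the complex to its targets. The series title names the maternally expressed Gtl2-Rian-Mirg locus, an imprinted region of chromosome 12 that carries many microRNAs. The labels list 27 samples of chromatin, messenger RNA and small RNA sequencing, of which 7 are small RNA samples: 2 for each of wild-type, Eed-/- and Ezh2-/-, and 1 for Jarid2-/-. The measurements reported here are microRNA counts from the small RNA samples, given as 1 column per genotype. The messenger RNA levels of Eed, Ezh2 and Jarid2, which would check the genotype labels, were not analysed here. The question addressed was which microRNAs, and in particular those of the Gtl2-Rian-Mirg locus, differed between cells lacking each protein and wild-type cells.

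Each column held counts for 2035 mature microRNA loci of miRBase release 20, placed on mouse genome build mm9. The wild-type column totalled 23793733 microRNA counts, the Eed-/- column 42293019, the Ezh2-/- column 32074712 and the Jarid2-/- column 8485806. Between 1224 loci (Jarid2-/-) and 1589 loci (Eed-/-) had at least 1 count. The highest level that a count of 0 allowed, taken as 3 counts, was 0.126 counts-per-million of all microRNA counts (CPM) in wild-type, 0.0709 in Eed-/-, 0.0935 in Ezh2-/- and 0.354 in Jarid2-/-. The miR-290 cluster, the most abundant microRNA group of mouse ES cells, made up 39.7% (39.72 to 39.76%) of microRNA counts in wild-type, 44.4% (44.43 to 44.46%) in Eed-/-, 45.9% (45.93 to 45.96%) in Ezh2-/- and 38.2% (38.15 to 38.22%) in Jarid2-/-. Because each genotype had a single column, no difference has a replicate check and no test between genotypes was possible. Ranges in parentheses after folds and shares are exact 95% binomial intervals. They cover counting error only, and reads amplified by PCR are not independent molecules, so the intervals are narrower than the true error. A locus was called higher or lower when its log2 ratio of CPM, with 1 CPM added to each value, was at least 1 in size, among tested loci, those with at least 10 counts in 1 of the 2 columns.

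MicroRNAs of the Gtl2-Rian-Mirg cluster were lower in all 3 mutants, and the summed difference ranged from 6.50-fold to 1013-fold. The cluster lies at chr12:110801920-110986159 (mm9), a span of 184240 bp. This span holds 115 microRNA loci, 109 on the plus and 6 on the minus strand, and 112 of the 115 belong to the cluster's list. The plus-strand microRNAs are processed from maternally expressed noncoding transcripts that include Gtl2 (Meg3), anti-Rtl1, Rian and Mirg. The cluster made up 4.86% (4.85 to 4.87%) of microRNA counts in wild-type cells. In Eed-/- cells the share was 0.747% (0.745 to 0.750%), in Jarid2-/- cells 0.278% (0.274 to 0.282%) and in Ezh2-/- cells 0.00480% (0.00456 to 0.00505%), the last from 1540 counts. Summed over the 103 tested members and scaled to total microRNA counts, the cluster was 6.50-fold lower (6.48 to 6.53) in Eed-/-, 17.5-fold lower (17.3 to 17.7) in Jarid2-/- and 1013-fold lower (964 to 1066) in Ezh2-/-. Of these members, 89 were at least 2-fold lower in Eed-/-, 97 in Jarid2-/- and 100 in Ezh2-/-, and 89 were lower in all 3.

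All 3 parts of the locus showed the lower level. Members from miR-770 to miR-136 (chr12:110801920-110833597), which include those of anti-Rtl1, were 7.43-fold lower (7.37 to 7.49) in Eed-/-, 1240.1-fold lower (1109 to 1391) in Ezh2-/- and 18.4-fold lower (17.9 to 18.9) in Jarid2-/-. The 5 members of the Rian part, miR-341 to miR-370 (chr12:110849731-110856536), were 6.47-fold (6.23 to 6.71), 556-fold (391 to 818) and 7.77-fold (7.15 to 8.45) lower in the same order. The 73 members of the Mirg part, miR-379 to miR-3072 (chr12:110947275-110986159), were 6.24-fold (6.21 to 6.27), 966-fold (913 to 1023) and 17.5-fold (17.3 to 17.8) lower. This split into parts was made after the values were seen.

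**Figure D1:**
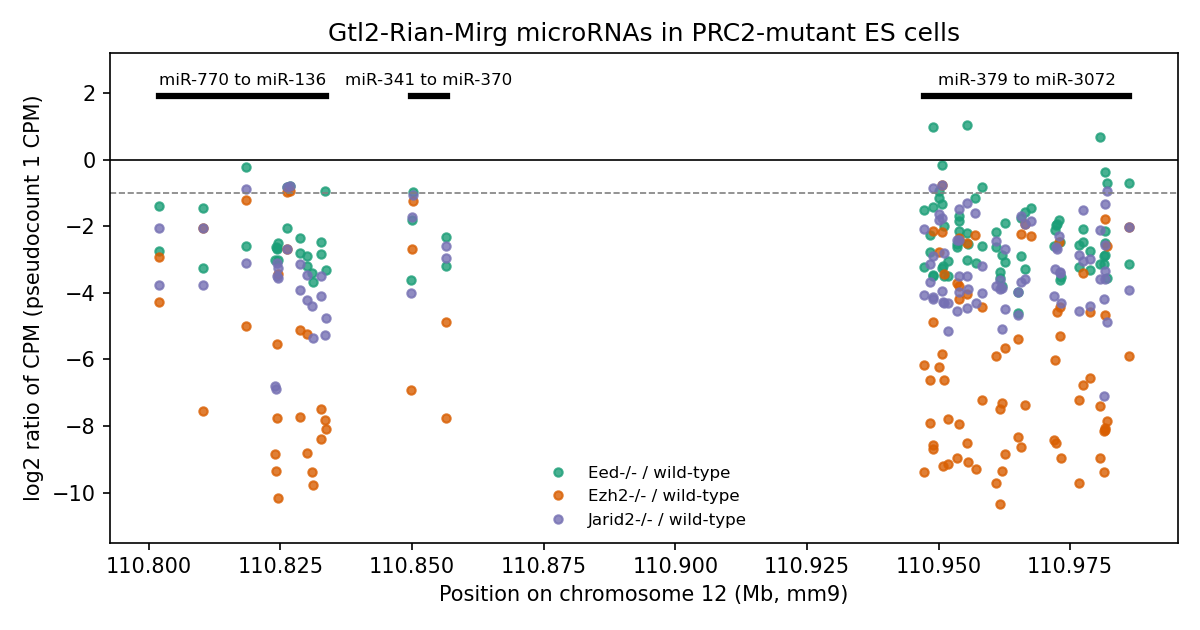
Log2 ratio of CPM (mutant over wild-type, 1 CPM added; vertical axis) against position on chromosome 12 in Mb (mm9; horizontal axis) for each tested microRNA of the Gtl2-Rian-Mirg cluster in the 3 mutants, with bars for the 3 parts of the locus and a dashed line at a log2 ratio of -1. The points lie mostly below the dashed line along the whole locus, with medians of -2.60 in Eed-/-, -3.49 in Jarid2-/- and -6.60 in Ezh2-/-.

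In Eed-/- cells compared with wild-type, cluster microRNAs were lower while the medians of the Hox, miR-290, miR-302, Sfmbt2 and let-7 groups were above wild-type. The median log2 ratio of the 103 Gtl2-Rian-Mirg members was -2.60 (quartiles -3.14 and -1.82). Among the most abundant members, miR-409-3p (chr12:110981414-110981435) had 24647 counts against 104289 in wild-type, which was 7.52-fold lower (7.42 to 7.63). MiR-127-3p (chr12:110831098-110831119), which lies antisense to the retrotransposon-like gene Rtl1, was 12.8-fold lower (12.5 to 13.2), and miR-376b-3p was 10.5-fold lower (10.3 to 10.6). The largest difference in the cluster was that of miR-381-3p, with 682 counts against 9856 and a level 25.7-fold lower (23.8 to 27.8). Not all members followed: miR-541-5p was 1.62-fold higher (1.59 to 1.64), with 58095 counts against 20219, and 14 of the 103 members were not called lower. Without the added 1 CPM, 5 of the 14 were more than 2-fold lower: miR-3070a-5p, miR-3070b-5p, miR-1188-3p, miR-380-5p and miR-3072-5p. Of the 14, 2 were chosen after their values were seen: miR-666-5p, with 450 counts against 111 and a level 2.28-fold higher (1.85 to 2.83), the only member called higher, and miR-299b-3p, with 327 against 81 and a level 2.27-fold higher (1.78 to 2.93), whose log2 ratio with 1 CPM added was 0.99.

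Outside the cluster, the microRNAs with the largest positive ratios in Eed-/- were miR-294-5p (chr7:3220656-3220677), 72.2-fold higher (69.3 to 75.2), and miR-7b-5p, 57.9-fold higher (52.8 to 63.6). MicroRNAs of the Hox gene clusters, classical PRC2 targets that pattern the body axis, had a median log2 ratio of 2.18 with 10 of 11 members higher. Among them miR-10b-5p (chr2:74564131-74564153) was 33.2-fold higher (29.9 to 36.9), miR-10a-5p 29.3-fold (25.5 to 33.7) and miR-196b-5p 21.2-fold (19.1 to 23.7). The 14 members of the miR-290 cluster had a median of 1.44, with 8 higher and 6 below 0, and their summed level was 1.12-fold higher (1.117 to 1.119). Here the 5p arm miR-294-5p stood far above wild-type while the abundant 3p arm miR-294-3p had a log2 ratio of -0.40. The miR-302 cluster, which is active in pluripotent and early differentiating cells, had a median of 1.04 with 5 of 10 higher, including miR-302a-3p at 2.91-fold (2.87 to 2.95). The placentally expressed Sfmbt2 intronic cluster had a median of 0.96 with 60 of 121 higher and 0 lower, and the let-7 family, whose mature forms accumulate during differentiation, had a median of 0.58 with 5 of 21 higher. Members of let-7 went both ways, with let-7c-5p 3.76-fold higher (3.42 to 4.14) and let-7g-5p 1.97-fold lower (1.88 to 2.06). The medians of these 5 groups lay above the central 95% of random lists matched on expression. Among the other groups, neural microRNAs had a median of 0.25 and other imprinted microRNAs 0.30, and both stayed positive under all scalings. The median was 0.11 for muscle and mesenchymal microRNAs (-0.03 with median-ratio scaling, and -0.55 and below the random range with at least 100 counts), -0.17 for the miR-17 family clusters, -0.18 for the miR-29 and miR-34 families, -0.20 for epithelial and endodermal microRNAs and -0.12 for blood cell microRNAs. With the RPM denominators of the authors the last 4 turned positive, at 0.54, 0.49, 0.41 and 0.49. The lowest ratios outside the cluster were those of miR-142-5p (chr11:87570369-87570389), a blood cell microRNA, with 103 counts against 5056 and a level 87.3-fold lower (71.8 to 107), and miR-142-3p, 49.5-fold lower (40.0 to 62.0). Of the epithelial group, miR-141-3p was 5.51-fold lower (5.40 to 5.63) and miR-200a-3p 2.82-fold lower (2.79 to 2.86). MiR-93-5p, a member of the miR-17 family clusters, was 30.1-fold higher (29.2 to 31.1). Its log2 ratio exceeded that of the 3p arm of the same hairpin by 4.29.

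Among 1096 tested loci, 192 were higher and 164 lower in Eed-/-, or 191 and 75 outside the cluster. The cluster median lay below all 10000 random lists, whose central 95% ran from -0.00 to 0.52. The median of all tested loci was 0.08, and it moved to -0.06 with median-ratio size factors and to 0.52 with the RPM denominators. The split of higher against lower loci was then 131 against 196 and 369 against 110. Relative to the median of all loci, the cluster stood at -2.68, the Hox group at 2.10, the miR-290 cluster at 1.36, the miR-302 cluster at 0.96, the Sfmbt2 cluster at 0.88 and the let-7 family at 0.50, and each kept its sign under every scaling. Without multi-copy microRNAs, those with several loci or same-numbered relatives, 63 loci were higher, the miR-290 cluster median was -0.12, and fewer than 3 loci of the Hox, Sfmbt2, miR-302 and let-7 groups were left. With arms and copies summed per hairpin, the miR-290, miR-302 and let-7 medians (-0.04, 1.00 and 0.37) lay within the random range, and without a count filter those of the miR-290 cluster and the let-7 family (0.16 and 0.39) did. The miR-302 median (1.08) also lay within it with at least 100 counts, and the let-7 median (0.54) with 1 value per mature name.

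In Ezh2-/- cells the Gtl2-Rian-Mirg microRNAs were close to undetected, and the medians of the other groups lay within 1 log2 unit of wild-type. The 10 most abundant members kept between 23 and 181 counts. MiR-409-3p had 181 counts against 104289 in wild-type, 777-fold lower (671 to 904), miR-376b-3p had 57 against 85950, 2033-fold lower (1569 to 2684), and miR-127-3p had 39 against 46523, 1608-fold lower (1176 to 2262). Of the 103 tested members, 100 were at least 2-fold lower and 31 had 0 counts. The other 3, miR-1197-5p, miR-3070a-5p and miR-3070b-5p, chosen after their values were seen, had 0 counts against 17 to 23 in wild-type, below what the added 1 CPM lets be called. The median log2 ratio was -6.60 (quartiles -8.40 and -3.75). The added 1 CPM bounds this value, which was -8.94 with 0.1 CPM added and -3.45 with 10. With nothing added and the members at 0 counts set to the floor of 3 counts, the median was -9.39.

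Outside the cluster, the 2 arms of miR-291b, a member of the miR-290 cluster, were higher in Ezh2-/-, with miR-291b-3p at 37.0-fold (36.1 to 37.9) and miR-291b-5p at 4.21-fold (4.10 to 4.32). The miR-290 cluster as a whole had 4 of 14 members higher and 2 lower, with a median of 0.09. Epithelial and endodermal microRNAs had a median of 0.11, with 5 of 21 higher, including miR-200c-3p (chr6:124668342-124668364) at 6.95-fold (6.0 to 8.09), miR-200b-3p at 4.45-fold (4.25 to 4.66) and miR-192-5p at 3.04-fold (2.98 to 3.11). In the same group miR-205-5p (chr1:195333697-195333718), a microRNA of stratified epithelia, was 10.6-fold lower (10.3 to 10.9). The miR-17 family clusters, abundant in proliferating cells, had a median of 0.18 with 3 of 30 higher and 3 lower. Neural microRNAs had a median of -0.02, which was positive under every other scaling (0.65 with TMM), with 5 of 36 higher and 6 lower. In this group miR-218-5p was 6.89-fold lower (6.66 to 7.12) and the 3 loci of miR-124-3p were 1.58-fold higher (1.55 to 1.60). The Sfmbt2 intronic cluster had a median of -0.67, or 0.01 with TMM, with 19 of 118 lower and 1 higher, and miR-466b-3p was 3.31-fold lower (3.25 to 3.37). The medians of the miR-290, miR-17, epithelial and neural groups lay above the central 95% of matched random lists and that of the Sfmbt2 cluster below it, but the miR-290 median (0.08) lay within the range with 1 value per mature name.

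The remaining groups in Ezh2-/- lay within the random range. Hox cluster microRNAs had a median of 0.11 with 0 of 8 higher and 0 lower, and lay above the range with TMM (0.74), median-ratio size factors (0.58) and the RPM denominators (0.53). Medians were -0.48 for the miR-302 cluster, -0.40 for the let-7 family, -0.49 for the miR-29 and miR-34 families, -0.72 for muscle and mesenchymal microRNAs, -0.73 for other imprinted microRNAs and 0.18 for blood cell microRNAs. With TMM the miR-302, let-7 and miR-29 and miR-34 medians turned positive, at 0.23, 0.14 and 0.15, and the imprinted and muscle medians moved to -0.06 and -0.21. Of the imprinted group, miR-298-5p, which lies near the Gnas locus, was 4.74-fold lower (4.64 to 4.84) and miR-296-3p 2.11-fold lower (2.02 to 2.21). Among 1000 tested loci, 49 were higher and 245 lower, or 49 and 145 outside the cluster. This split depended on the scaling, since the median of all loci was -0.44 with total counts, 0.09 with TMM, -0.07 with median-ratio size factors and -0.13 with the RPM denominators. With these scalings 145, 111 and 101 loci were higher and 163, 189 and 194 lower. Relative to the median of all loci, the cluster stood at -6.16, the Sfmbt2 cluster at -0.23, the miR-17 family clusters at 0.63, epithelial microRNAs at 0.55, the miR-290 cluster at 0.53 and neural microRNAs at 0.42. Without multi-copy microRNAs 24 loci were higher and 153 lower, the miR-290 cluster median was -0.12, and of the groups outside the cluster that of blood cell microRNAs, at 0.72, lay outside the random range. Summed per hairpin, the Sfmbt2, miR-17 and neural medians (-0.71, 0.07 and -0.35) lay within it.

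In Jarid2-/- cells the Gtl2-Rian-Mirg microRNAs were lower, the median of Hox cluster microRNAs was lower as well, and the medians of the Sfmbt2, miR-302 and let-7 groups were higher. The miR-290 cluster had a higher median but a summed level 1.04-fold lower (1.039 to 1.042). Of the 103 tested cluster members, 97 were at least 2-fold lower, with a median log2 ratio of -3.49 (quartiles -4.10 and -2.42), or -3.68 with nothing added and the 5 members at 0 counts set to the floor. The size of the difference varied within the cluster. MiR-409-3p had 262 counts against 104289 and was 142-fold lower (126 to 161), and miR-337-3p and miR-337-5p were 131.5-fold (105 to 168) and 127-fold (98.2 to 166) lower. MiR-127-3p was 42.2-fold lower (38.2 to 46.7), while miR-665-3p was 11.7-fold (11.2 to 12.1) and miR-541-5p 4.33-fold (4.11 to 4.55) lower.

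Outside the cluster, the lowest ratios in Jarid2-/- belonged to the 3 loci of the neural microRNA miR-124-3p, for example 128 counts against 24124, 67.2-fold lower (56.5 to 80.6). They were followed by miR-22-3p (chr11:75277274-75277295), 50.5-fold lower (40.7 to 63.3), and the hypoxia-induced miR-210-3p (chr7:148407306-148407327), 40.2-fold lower (37.3 to 43.4). The other arm of that hairpin, miR-210-5p, had a log2 ratio of -1.18, so the 2 arms differed in size. Hox cluster microRNAs had a median of -2.0, with 4 of 7 tested members lower and 0 higher. MiR-196a-5p had 20 counts against 1923 at its chromosome 11 locus, 34.3-fold lower (22.1 to 56.3), miR-196b-5p was 6.49-fold lower (4.10 to 10.9), and miR-10b-5p had a log2 ratio of -0.31. The Sfmbt2 intronic cluster had a median of 0.80 with 48 of 119 higher and 0 lower. Its member miR-466o-3p was 72.2-fold higher (64.0 to 81.7), and miR-466b-3p was 2.33-fold higher (2.30 to 2.37). The miR-302 cluster had a median of 1.20 with 6 of 10 higher, and the miR-290 cluster 0.84 with 6 of 14 members higher and 1 lower, including miR-294-5p at 39.4-fold (37.8 to 41.1) and miR-295-5p at 31.4-fold (29.9 to 33.1). The let-7 family had a median of 0.92 with 8 of 19 higher and 1 lower, and let-7c-5p was 6.60-fold higher (5.94 to 7.34). Over the alternatives the let-7 median ran from 0.37 with 1 value per mature name to 1.64 with at least 100 counts. These 4 medians lay above the central 95% of matched random lists and that of the Hox group below it, but that of the miR-290 cluster lay within it under 5 alternatives, among them no count filter (percentile 89.0) and at least 100 counts (95.9).

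The other groups in Jarid2-/- lay within the random range, although muscle and mesenchymal microRNAs lay below it under 5 alternatives and the miR-17 family clusters above it under 2. Medians were 0.53 for the miR-17 family clusters, 0.12 for epithelial and endodermal microRNAs, -0.08 for neural microRNAs (0.30 with the RPM denominators), -0.66 for muscle and mesenchymal microRNAs, -0.93 for blood cell microRNAs, -0.48 for other imprinted microRNAs and -0.70 for the miR-29 and miR-34 families. In these groups miR-205-5p was 2.63-fold higher (2.59 to 2.67), miR-31-5p 3.79-fold lower (3.52 to 4.08), miR-142-5p 5.41-fold lower (4.85 to 6.07) and miR-34a-5p, a microRNA induced by p53, 2.40-fold lower (2.37 to 2.42). Among 950 tested loci, 155 were higher and 217 lower, or 155 and 120 outside the cluster. The median of all loci was -0.17, and with the RPM denominators, where it was 0.23, 259 loci were higher and 184 lower. Relative to the median of all loci, the cluster stood at -3.32, the Hox group at -1.82, the Sfmbt2 cluster at 0.97, the miR-302 cluster at 1.37, the miR-290 cluster at 1.02 and the let-7 family at 1.10, and each kept its sign under every scaling. The Hox result was fragile: its percentile of 1.54 rested on 7 loci, miR-196a-5p being 2 of them, and it lay within the random range under 8 alternatives. Among these were TMM (percentile 2.50), no count filter (median -0.28), a pseudocount of 10 (-0.75) and summing per hairpin (-0.61, percentile 30.4). The miR-290 and miR-302 medians (0.19 and 0.84) also lay within that range per hairpin, and without multi-copy microRNAs 53 loci were higher, 141 lower and the miR-290 median 0.00.

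The Eed-/- and Jarid2-/- columns, in which the miR-290, Sfmbt2, miR-302 and let-7 medians were above wild-type, also shared a pattern between the 2 arms of single hairpins. Across 84 hairpins with both arms measured, the 5p minus 3p difference in the log2 ratio of Eed-/- over wild-type had a Pearson correlation of 0.49 (95% bootstrap interval 0.157 to 0.708; Spearman's rho 0.33) with that of Jarid2-/- over Ezh2-/-, a pair of ratios that share no column. Without miR-294 and miR-93 it was 0.37, and without the 7 hairpins of the miR-290 cluster 0.24 (-0.04 to 0.50). The other such pairing, Eed-/- over Ezh2-/- with Jarid2-/- over wild-type, gave 0.44 (0.17 to 0.66). Without the miR-290 hairpins it gave 0.24 (0.05 to 0.45). This pairing uses the same columns as the first. It follows largely from the first, because the remaining pairing, Eed-/- over Jarid2-/- with Ezh2-/- over wild-type, gave -0.03. It is thus not separate evidence. The miR-290 hairpins, in which the pattern was first seen, held the largest shared differences, such as 6.58 and 7.89 for miR-294 and 3.58 and 5.81 for miR-295. The high ratios of miR-294-5p and miR-295-5p are thus part of what prompted the comparison, not separate evidence for the pattern. Hairpins are not independent replicates, no let-7 hairpin was among them, and how far the ratios of the other groups follow this pattern was not tested. All 128 loci of the Sfmbt2 list, 22 of 24 of the let-7 family, 8 of 10 of the miR-302 cluster, 12 of 18 of the miR-290 cluster and 10 of 12 of the Hox list belong to microRNAs with several loci or same-numbered lettered relatives. Names with more than 1 locus mostly had near-equal counts at each, from counting at each locus or an even split, and whether reads were shared between lettered relatives was not tested.

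**Figure D2:**
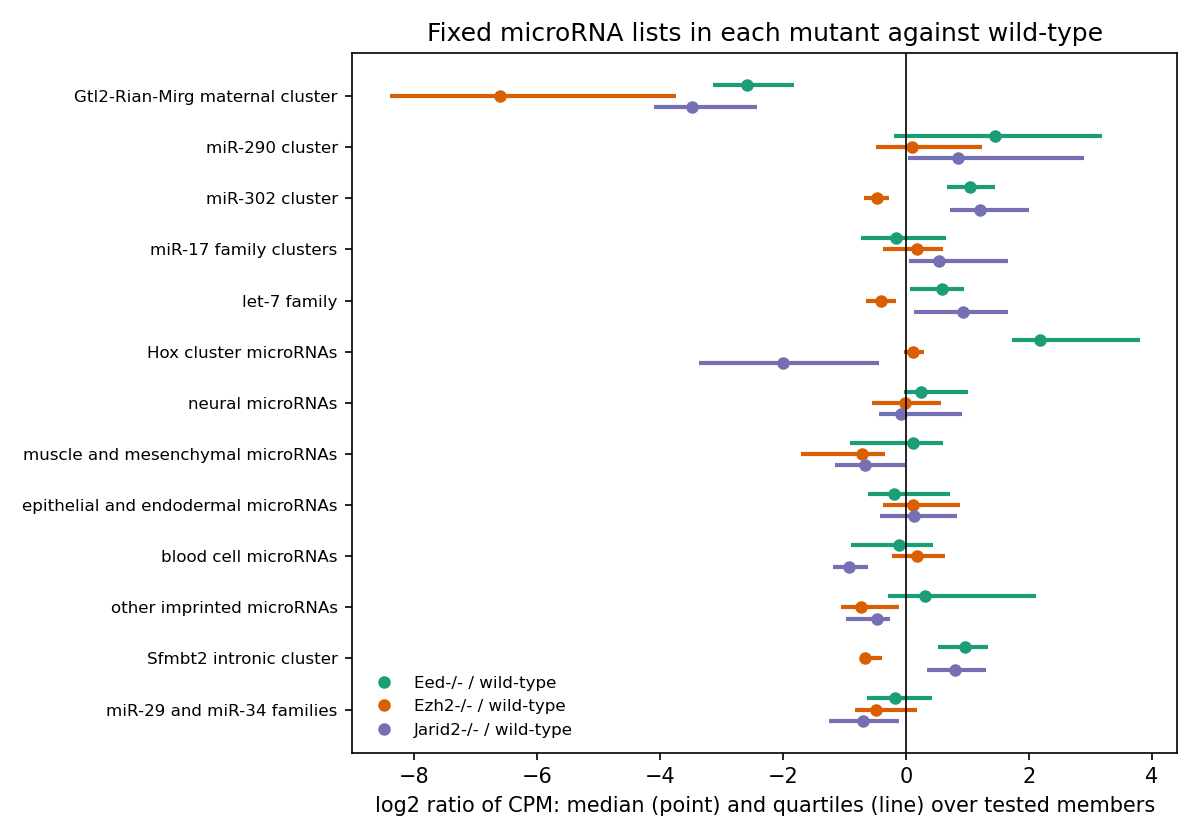
Median log2 ratio of CPM (mutant over wild-type, horizontal axis) of the tested members of the 13 microRNA groups, with lines from the lower to the upper quartile, for the 3 mutants. The Gtl2-Rian-Mirg cluster is the lowest group in each mutant (-2.60, -6.60 and -3.49), and Hox cluster microRNAs lie at 2.18 in Eed-/- and at -2.0 in Jarid2-/-; in Ezh2-/- the medians of the Sfmbt2, miR-302, let-7, neural, and miR-29 and miR-34 groups turn to 0.01, 0.23, 0.14, 0.65 and 0.15 with TMM scaling.

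**Figure D3:**
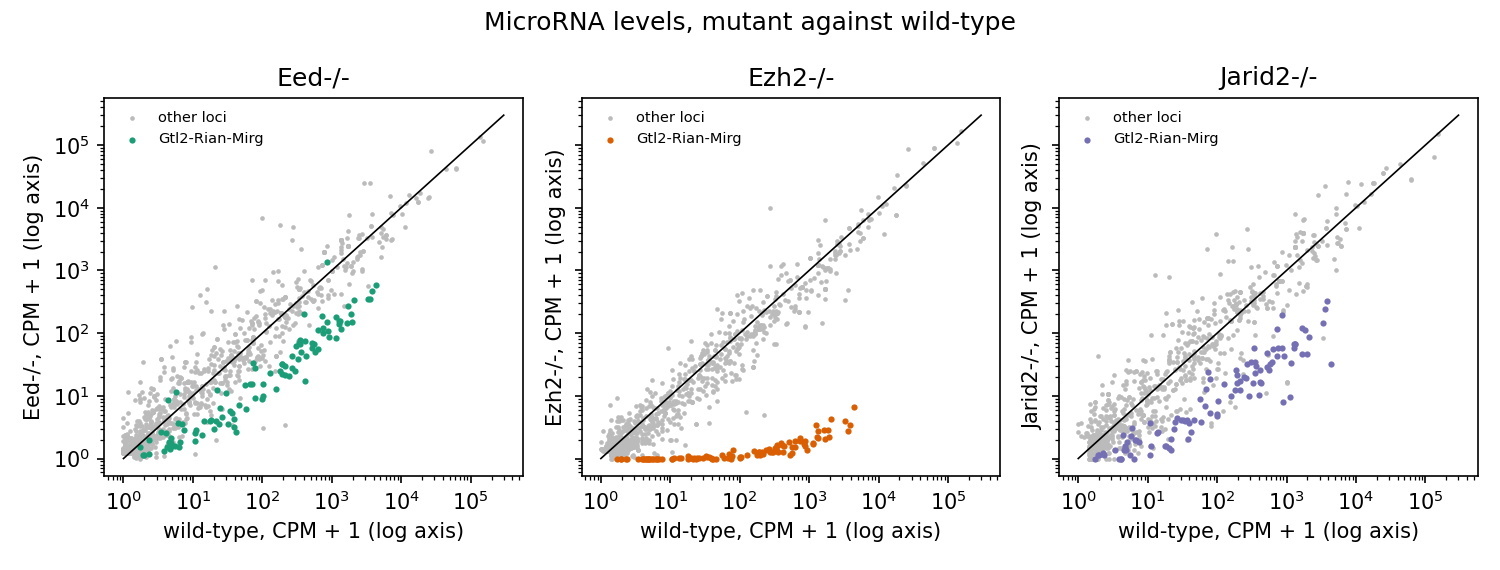
CPM plus 1 of each mutant (vertical axis) against wild-type (horizontal axis), both on log scales, for the tested loci of each mutant, with Gtl2-Rian-Mirg members coloured. Of the 103 coloured loci, 89 lie at least 2-fold below equality in Eed-/-, 100 in Ezh2-/- and 97 in Jarid2-/-.

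The mutants also differed from each other in the cluster, a set of comparisons that leaves out the wild-type column. Cluster microRNAs were 155.8-fold higher (148 to 164) in Eed-/- than in Ezh2-/-, with 88 of 100 tested members at least 2-fold higher and a median log2 ratio of 3.92. They were 58.0-fold higher (55.1 to 61.1) in Jarid2-/- than in Ezh2-/-, with 76 of 76 members higher and a median of 3.8, and 2.69-fold lower (2.65 to 2.72) in Jarid2-/- than in Eed-/-, with 38 of 100 members lower and a median of -0.78. Testing needed at least 10 counts in 1 of the 2 columns. Members with fewer in Ezh2-/- passed only through the other column. The counts of members higher than in Ezh2-/-, and the medians of these comparisons, are therefore partly set by the filter. MiR-541-5p was 1916-fold higher (1277 to 3022) in Eed-/- than in Ezh2-/-, and miR-665-3p was 198-fold higher (158 to 251). In Jarid2-/- over Ezh2-/- the same microRNAs were 274-fold (182 to 433) and 138-fold (110 to 176) higher.

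Hox cluster microRNAs separated Jarid2-/- from Eed-/-, with 10 of 11 members lower, a median of -3.52 and a summed level 62.0-fold lower (54.6 to 70.6). Only 7 Hox loci had passed the filter in Jarid2-/- against wild-type, so the others passed here through Eed-/- alone. The Hox count and median in Jarid2-/- over Eed-/- are therefore partly set by the filter. MiR-196b-5p was 138-fold lower (88.2 to 229) and miR-124-3p 65.7-fold lower (55.3 to 78.8), while miR-142-5p was 16.1-fold higher (12.9 to 20.3) and let-7d-5p, of the let-7 family, 4.78-fold higher (4.40 to 5.19). Between Eed-/- and Ezh2-/- the Hox median was 2.36 with 10 of 11 higher, the miR-302 median 1.64, the Sfmbt2 median 1.47 with 97 of 121 higher, and the let-7 median 1.04. With TMM the last 3 were 0.78, 0.96 and 0.41. The Hox count and median are partly set by the filter here too, since only 8 Hox loci had passed in Ezh2-/- against wild-type. In that comparison miR-294-5p was 398-fold higher (367 to 434) and miR-142-5p 55.0-fold lower (45.2 to 67.5). Between Jarid2-/- and Ezh2-/- the let-7 median was 1.96, the miR-302 median 1.81, the Sfmbt2 median 1.32 and the Hox median -1.56, or 1.22, 1.06, 0.57 and -2.20 with TMM. Here miR-294-5p was 217.5-fold higher (200.1 to 237), while miR-124-3p was 106-fold (89.1 to 127) and miR-22-3p 33.2-fold (26.8 to 41.7) lower. In total 390 of 1091 loci were higher and 50 lower in Eed-/- than in Ezh2-/-, which became 246 and 192 with TMM and 273 and 163 with median-ratio size factors. In Jarid2-/- 77 of 1073 loci were higher and 203 lower than in Eed-/-. Against Ezh2-/- 307 of 930 loci were higher and 83 lower in Jarid2-/-, or 223 and 207 with TMM and 231 and 182 with median-ratio size factors. With other scalings the median of all loci moved in the comparisons with Ezh2-/-, from 0.41 to 0.01 for Eed-/- and from 0.33 to -0.19 for Jarid2-/- with TMM, and for Jarid2-/- over Eed-/- it moved from -0.21 to -0.38 with the RPM denominators. Relative to it, the cluster stood at 3.51 in Eed-/- over Ezh2-/-, 3.47 in Jarid2-/- over Ezh2-/- and -0.57 in Jarid2-/- over Eed-/-, and the Hox group at 1.95, -1.89 and -3.31. The group medians given for these comparisons kept their sign under every scaling.

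Loci outside the cluster that were called in more than 1 mutant were counted among the 841 loci tested in all 3. Eed-/- and Jarid2-/- shared 82 higher loci, where independent lists would share 32.2, and 38 lower loci (10.7 for independent lists). Eed-/- and Ezh2-/- shared 17 higher (9.95) and 36 lower loci (12.9), and Ezh2-/- and Jarid2-/- shared 22 higher (8.49) and 45 lower loci (20.7). All 3 mutants shared 7 higher loci (1.80), among them miR-291b-3p and miR-672-5p, and 22 lower loci (1.85), among them miR-210-3p and miR-145a-5p. Simulated unchanged columns compared with the same wild-type column shared 0 in each case. They carry counting error only, which called 0% of unchanged loci in the simulated test. Their value of 0 was thus nearly fixed in advance and sets no baseline for the overlaps. Part of the excess may come from the shared wild-type column, which could not be split. Independent lists also treat each locus as a separate unit, although copies of a microRNA were counted as separate loci. The Sfmbt2 group, all multi-copy, alone held 60 of 121 tested loci higher in Eed-/- and 48 of 119 in Jarid2-/-. The overlaps were not recounted without multi-copy loci. Within the cluster, 89 of 103 members were lower in all 3, where independent lists would share 81.4.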

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

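The tests of other genomic clusters, carry-over and shared library preparation, the explanation by differences between cell lines, and the scaling by RPM denominators were chosen only after group medians, counts of the locus or ratios of miR-290 arms were seen. Medians of several of the 8 other clusters were then already known.

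The lower Gtl2-Rian-Mirg microRNAs in all 3 mutants are the main pattern. The tables argue against scaling, since the highest cluster median over the other scalings was -1.92, against reads counted at several loci, since the highest median without multi-copy loci was -2.60, and against a loss common to microRNA clusters, since 0 of 8 other genomic clusters had a median of -1 or lower in all 3 mutants. The absence of the PRC2 proteins, which the design names, stays open as a hypothesis. Differences between cell lines unrelated to the mutated gene, such as altered imprinting acquired in culture, cannot be told apart from it with 1 column per genotype.

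The Ezh2-/- column kept 1540 reads of the cluster. Carry-over from another column would give counts proportional to that column's, but the chi-square over its degrees of freedom (near 1 if proportional, with an SD of 0.202, or 0.213 for Eed-/-) was 5.11 for wild-type, 13.6 for Eed-/- and 45.1 for Jarid2-/-. Equal carry-over of all reads from a single donor column thus departs from the counts by more than counting error. Amplification beyond counting error also raises these values and was not separated. The test therefore cannot say how likely such carry-over is. Log counts of the members still correlated with those of each column. Pearson's r was 0.85 for wild-type, 0.86 for Eed-/- and 0.87 for Jarid2-/-, so partial carry-over stays open. Low expression in some or all cells stays open and was not tested.

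The Eed-/- and Jarid2-/- columns deviated together from wild-type and Ezh2-/-. The 5p minus 3p differences correlated across hairpins at 0.49, against -0.03 for the control pairing of Eed-/- over Jarid2-/- with Ezh2-/- over wild-type. A change in transcription of a hairpin leaves these differences at 0 only if each arm's reads come from that hairpin alone. Whether lettered relatives shared reads was not tested. The pattern was first seen in the miR-290 cluster, and across the 77 hairpins outside it the correlation was 0.24 (-0.04 to 0.50). A second pairing without a common column, Eed-/- over Ezh2-/- with Jarid2-/- over wild-type, gave 0.44 over all hairpins. Outside the miR-290 cluster it gave 0.24 (0.05 to 0.45). This pairing uses the same columns and follows largely from the first, because the control pairing was weak (-0.03, and 0.01 outside the miR-290 cluster). It is thus not separate evidence. Library preparation or sequencing shared by Eed-/- and Jarid2-/-, which would give such correlations, cannot be told apart from other causes at this size. GC content and length of the mature sequence were compared with the ratios by Spearman's rho over 834 loci outside the Gtl2-Rian-Mirg cluster. For GC content, rho was -0.165 (bootstrap interval -0.230 to -0.106) in Eed-/- over wild-type and -0.177 (-0.245 to -0.109) in Jarid2-/- over Ezh2-/-. For length it was 0.141 (0.082 to 0.208) and 0.148 (0.085 to 0.213). These values argue against a steady trend with either property as the main source across these loci. A smaller contribution stays open. The miR-290 cluster held the largest differences, 6.58 (Eed-/- over wild-type) and 7.89 (Jarid2-/- over Ezh2-/-) for miR-294. The large ratios of miR-294-5p are thus part of what prompted the comparison, not separate evidence for the pattern. Whether the higher Sfmbt2, miR-302 and let-7 medians of both mutants share the source of this pattern was not tested, and arm selection that differs between the cells stays open.

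The following values stood out because 2 mutants lay on opposite sides of wild-type, each by at least 2-fold. The differences between mutants were not tested, since each genotype had 1 column. The median log2 ratio of Hox cluster microRNAs was 4.17 higher in Eed-/- (11 tested loci) than in Jarid2-/- (7 tested loci). The direct ratio of Jarid2-/- over Eed-/- had a median of -3.52 over 11 loci, some of which passed the filter only through Eed-/-. The Jarid2-/- median was less than 2-fold lower with no count filter (-0.28) and per hairpin (-0.61). Among 89 named microRNAs, 12 lay on opposite sides of wild-type in this way, in 17 pairs of mutants. Eed-/- minus Jarid2-/- was 6.59 for miR-196a-5p, 6.58 for miR-196b-5p and 4.52 for miR-31-5p. Eed-/- minus Ezh2-/- was 8.56 for miR-294-5p, 6.32 for miR-466o-3p, 3.29 for miR-126b-5p, -2.84 for miR-6375 and -2.65 for miR-6398. Ezh2-/- minus Jarid2-/- was -7.69 for miR-294-5p, -7.36 for miR-466o-3p, -4.79 for miR-205-5p, -4.69 for miR-126b-5p, -2.95 for miR-466b-3p, miR-466c-3p and miR-466e-3p, 2.96 for miR-31-5p and 3.08 for miR-6398.

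The RPM columns, used in the comparisons only as an alternative scaling, held another difference. MicroRNAs were 15.8% of the RPM denominator in Eed-/-, 13.2% in Ezh2-/- and 13.6% in Jarid2-/-, all above the 9.66% in wild-type. If reads were counted at each locus, multi-copy microRNAs would add to these percentages, which was not tested. No group had 4 or more samples, so none was examined for a sample far from the others.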

How the results depend on the processing

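The RPM denominators, 1 value per mature name and thinning were chosen as alternatives only after the data were seen. The Gtl2-Rian-Mirg cluster was lower in each mutant under all 13 alternatives, and below all matched random lists in the 12 where such lists were drawn (not for membership by position), with medians from -2.80 to -1.92 in Eed-/-, -8.94 to -3.45 in Ezh2-/- and -3.87 to -2.48 in Jarid2-/-. Membership by position on chromosome 12 moved none of its medians or counts of lower members beyond their bounds. Of 262 alternative values that answer a comparison, 176 stayed within 1.5 times the reported count or within counting error and 86 did not: 46 counts became smaller, 14 larger, and 26 medians or shares moved. The sign changed in 29 of the alternative medians of groups and was kept in 388. In 9 of the 29 the group had lain outside the random range, and these are given below. Among alternative values of single named microRNAs 67 changed sign, all with a reported log2 ratio of at most 0.69 in size. Outside the random range only under an alternative were Hox microRNAs in Ezh2-/- (3 alternatives), muscle and mesenchymal microRNAs in Eed-/- (1) and Jarid2-/- (5), miR-17 family clusters in Jarid2-/- (2) and blood cell microRNAs in Ezh2-/- (1). No paired analysis was possible because each genotype has a single column, and those of wild-type, Eed-/- and Ezh2-/- carry no replicate number. For the same reason the DESeq2 Wald test, leaving out replicates, the replicate block, and set tests with an estimated correlation were not run. The Jarid2-/- column, with 8485806 counts, limits how small a level could be seen, and with 0.1 CPM added, ratios of loci near the floor rest on few counts. Unless stated, the cause of the shifts below was not tested.

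In these values a pair of counts is the number of loci higher and lower. With TMM, the Eed-/- cluster median was -2.70, and in Ezh2-/- the Sfmbt2 and neural medians turned positive, at 0.013 and 0.65. Counts were 145 and 163 in Ezh2-/-, 246 and 192 for Eed-/- over Ezh2-/-, and 207 lower for Jarid2-/- over Ezh2-/-. With median-ratio size factors, cluster medians were -2.78 in Eed-/- and -3.55 in Jarid2-/-, the Ezh2-/- neural median was 0.46, 111 loci were higher in Ezh2-/-, 163 lower for Eed-/- over Ezh2-/-, and 182 lower for Jarid2-/- over Ezh2-/-. Scaling outside the clusters gave a Jarid2-/- cluster median of -3.56 and an Ezh2-/- neural median of 0.011. With the RPM denominators, cluster medians were -1.92 in Eed-/- and -3.09 in Jarid2-/-, the Ezh2-/- neural median was 0.39, and 369, 101 and 259 loci were higher in Eed-/-, Ezh2-/- and Jarid2-/-, with 29 lower for Eed-/- over Ezh2-/-.

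With at least 100 counts, cluster medians were -2.70, -7.38 and -3.60 in Eed-/-, Ezh2-/- and Jarid2-/-, the Ezh2-/- neural median was 0.0056, and 3 other groups lay outside the random range in Jarid2-/-. With no filter beyond 1 count, cluster medians were -2.53 in Eed-/- and -6.22 in Ezh2-/-, and 3 other groups lay outside the range in Eed-/-. With a pseudocount of 0.1, cluster medians were -2.80, -8.94 and -3.82, 87 loci were higher in Ezh2-/-, 91 lower for Eed-/- over Ezh2-/-, 118 higher and 309 lower for Jarid2-/- over Eed-/-, and 145 lower for Jarid2-/- over Ezh2-/-. With a pseudocount of 10, which by construction shrinks ratios of low loci, cluster medians were -2.09, -3.45 and -2.48. Counts were 105 higher in Eed-/-, 26 and 160 in Ezh2-/-, 95 higher in Jarid2-/-, 244 and 33 for Eed-/- over Ezh2-/-, 48 and 107 for Jarid2-/- over Eed-/-, and 42 lower for Jarid2-/- over Ezh2-/-, and 3 other groups lay outside the range in Jarid2-/-.

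Without multi-copy loci fewer loci were counted, and counts were 63 higher in Eed-/-, 24 and 153 in Ezh2-/-, 53 and 141 in Jarid2-/-, 174 and 21 for Eed-/- over Ezh2-/-, 36 and 105 for Jarid2-/- over Eed-/-, and 138 and 40 for Jarid2-/- over Ezh2-/-. The miR-290 medians turned to -0.12 in Eed-/- and -0.12 in Ezh2-/-. The Hox, Sfmbt2, miR-302, let-7, and miR-29 and miR-34 groups had fewer than 3 loci left and no value. Of the rest, 0 lay outside the random range in Eed-/-, 1 in Ezh2-/- (blood cell microRNAs) and 1 in Jarid2-/- (muscle and mesenchymal microRNAs, at -1.91). Summed per hairpin, which also leaves fewer values, cluster medians were -2.79, -8.48 and -3.87 with 51, 53 and 52 members lower in Eed-/-, Ezh2-/- and Jarid2-/-. Counts were 83 and 103 in Eed-/-, 30 and 141 in Ezh2-/-, 79 and 128 in Jarid2-/-, 197 and 25 for Eed-/- over Ezh2-/-, 43 and 114 for Jarid2-/- over Eed-/-, and 156 and 46 for Jarid2-/- over Ezh2-/-. The Eed-/- miR-290 median was -0.041, and 2 other groups lay outside the range in Eed-/- and 2 in Ezh2-/-. The Ezh2-/- cluster median was -6.87 with 1 value per mature name and -6.93 after thinning. Without the miR-290 cluster in the denominator, the cluster's share was 8.06% in wild-type, 1.35% in Eed-/-, 0.00888% in Ezh2-/- and 0.450% in Jarid2-/-.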

Other observations

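The clusters and microRNAs in this part, and the hypothesis on cell lines, were chosen only after their values were seen. Of 8 other genomic microRNA clusters, 1 had a median log2 ratio below -1 in any mutant. It was the X-linked cluster from miR-450b to miR-322 (chrX:50401185-50407504), whose microRNAs are linked to muscle differentiation and growth control, with medians of -0.18 in Eed-/-, -0.20 in Ezh2-/- and -1.22 in Jarid2-/-. MiR-322-5p had 24143 counts in wild-type, 61713 in Eed-/-, 22210 in Ezh2-/- and 2343 in Jarid2-/-, with log2 ratios of 0.52, -0.55 and -1.87. MiR-542-3p had 157 counts in Jarid2-/- against 2272 in wild-type, a log2 ratio of -2.31. Members of this cluster did not move together in Eed-/-, where miR-503-5p had a ratio of 2.84 and miR-351-5p of 2.11, while miR-542-5p stood at -1.23. Other X-linked clusters differed between mutants, with medians of 0.69, -0.75 and -0.57 for miR-743a to miR-465a (chrX:64029935-64092296) and 0.87, -0.81 and 0.24 for miR-500 to miR-532 (chrX:6814821-6825603) in Eed-/-, Ezh2-/- and Jarid2-/-.

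Outside the Gtl2-Rian-Mirg cluster, 22 loci were lower in all 3 mutants. The related miR-204-5p and miR-211-5p, which are found in pigment and retinal cells and share a seed sequence, had log2 ratios of -1.57 and -2.03 in Eed-/-, -3.26 and -4.45 in Ezh2-/-, and -2.71 and -4.43 in Jarid2-/-. MiR-211-5p had 2906 counts in wild-type and 1232, 148 and 40 in the mutants. The smooth muscle microRNAs miR-143-3p and miR-145a-5p, neighbours on chromosome 18, had ratios of -1.82 and -1.37, -2.03 and -1.22, and -4.78 and -1.16 in the same order, and the hypoxia-induced miR-210-3p had -2.58, -3.30 and -5.31. MiR-27a-3p stood at -1.31, -1.28 and -2.03. Of the 7 loci higher in all 3, miR-291b-3p had ratios of 3.48, 5.20 and 4.08, miR-672-5p, on the X chromosome, 2.71, 1.99 and 3.03, and miR-20a-5p 1.30, 1.91 and 1.93. All of these are measured against the same wild-type column, so a feature of that column would appear in each mutant.

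A hypothesis is that PRC2 is needed to keep the maternal Gtl2-Rian-Mirg transcripts active in these cells, with a stronger dependence on Ezh2 than on Eed. The lower level held under other scalings (highest median -1.92) and was seen in each part of the locus. Not all members followed in Eed-/-, where 89 of 103 were called lower and miR-541-5p was 1.62-fold higher. It was shared by 0 of 8 other clusters. That scan was chosen after several of their medians were known, and it cannot show whether the whole of this locus changed. Since Eed is needed for the stability and activity of the complex, a cluster 155.8-fold higher in Eed-/- than in Ezh2-/- is not what a simple loss of the complex predicts, and with 1 column per genotype a difference between the lines may account for it. Further replicate lines of each genotype would help to separate these explanations.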
